A study of Mus musculus with 11 samples.

How the data were processed

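RNA was measured with Affymetrix whole-genome mouse arrays in open neuroepithelium and closed neural tube of C57BL/6 mouse embryos at E8.5 and E9.5. Per the labels, the tissue was detached after incubation in 2.5% pancreatin and 0.5% trypsin for 5 min (E8.5) or 8 min (E9.5), together with closely attached notochord. Open tissue was taken caudal to the junction of open and closed neural tube, and closed tissue rostral to it. Tissue was pooled by litter (111 embryos in all). The arrays of a group were taken as separate biological replicates, and the labels do not say whether open and closed arrays share litters. From each sample 50 ng of RNA was labelled with a 2-cycle protocol. The authors hybridized 12 arrays and removed 1 closed E8.5 array for its quality, which leaves 11.

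The deposited table holds log2 signal of 45101 probe sets, from 2.37 to 14.717, with 0 missing values. Submitters' notes name MAS5 without a version or a role. The near-equal distributions of the arrays and the lowest values are not those of MAS5 signal on a log2 scale, so the background correction, summary and normalization behind the deposited log2 values are not known. The values were used as deposited. Detection calls were not used here.

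Of the probe sets, 34945 carried exactly 1 gene symbol. Those with several symbols (932), without one (9160) and the 64 control probe sets were left out of the tests. Each of 18193 genes was represented by its probe set of highest mean. Genes whose mean was at or above the 40th percentile of all probe sets (4.3, log2) were tested, 13341 in all. The 4 groups were fitted as 4 means in 1 linear model with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend), with 7 residual degrees of freedom and a median of 4.4 prior degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 were counted as past the threshold. The contrasts were closed minus open at E8.5, at E9.5 and over both stages, E9.5 minus E8.5 in open and in closed tissue, and the interaction of region and stage.

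Gene lists, 40 in number, were written before the data were examined, as were the contrasts, most alternatives and the rule for the genes to name. Of 13 tests of explanations and hypotheses, 6 were written before the results and 7 after them. They cover neural progenitor, neurogenesis, caudal progenitor, presomitic mesoderm, somite, lateral and intermediate mesoderm, notochord, floor plate and hedgehog response, dorsal neural tube and BMP response, neural crest, surface ectoderm and epithelium, endoderm, blood, endothelium, neural tube closure mutants, planar cell polarity, apical junction and actomyosin, claudins, extracellular matrix and integrins, retinoic acid pathway, FGF and MAPK feedback, Wnt response, Notch pathway, Hox genes in 3 lists by paralogue group, DNA replication, mitosis, cell cycle exit, early embryonic and let-7 regulated genes, folate and one-carbon, glycolysis, hypoxia response, oxidative phosphorylation, ribosomal protein, dissociation response, cholesterol synthesis, apoptosis, sex-linked genes and an anchor list of single genes of interest. The 38 lists with at least 5 tested genes, the anchor list aside, were tested with camera at a preset correlation of 0.01, adjusted over lists within a contrast. Members were counted past the threshold over all genes and adjusted over the list alone.

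Genes named for a contrast of regions or stages were the 8 largest differences in each direction among genes past the threshold whose groups do not overlap, the 2 members of smallest p in each direction of each list, of which examples are printed, and the anchor genes. For the interaction they were the 6 of smallest p in each direction and the anchor genes. For both stages together they were the anchor genes.

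Alternatives tried were quantile normalization, arrays centred on their median, no filter, a filter at the 60th percentile, the mean of all probe sets of a gene, all 27022 probe sets one by one, eBayes without a trend or with robust variances, array weights, a fit of only the groups compared, a block by replicate number, a limit of 1 on the absolute log2 difference, each array left out in turn, camera with an estimated correlation, and fry. Where 1 array of a group was left (without a closed E8.5 array, or without open E9.5 replicates 1 and 2 together), it was assumed to vary like the other groups. Of the alternatives, 3 were added after the data were seen: the 3-prime to 5-prime signal as a covariate, both arrays with the highest such signal left out, and the main component of the residuals as a covariate.

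Whether replicate numbers pair arrays was checked by correlating deviations from the group means across genes, which are not independent replicates. Open and closed arrays of the same number had correlations of 0.576 and 0.697 at E8.5 and 0.308, 0.341 and 0.687 at E9.5. Some pairs of different number were near these values: 0.264 for open 1 with closed 2 and 0.317 for open 2 with closed 1 at E9.5, and 0.308 for open 3 with closed 1 at E8.5. These correlations thus set replicate 3 apart at E9.5 but not replicates 1 and 2 from each other, which limits the blocked values. At E8.5 the 2 closed arrays deviate from their mean as mirror images, so that every open array has a positive value with 1 of them. Pairs of number 2 at E8.5 (1.153 and 1.184) and of number 3 at E9.5 (1.136 and 1.195) also had like 3-prime to 5-prime signal. The check cannot tell shared litters from shared RNA quality. Every same-number pair was above 0.1, so that blocks by number and stage were tried for the regions. The pairing comes from the numbers in the sample titles, and the labels do not state that they mark litters. Between stages the same numbers do not pair arrays.

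The test was checked on simulated data with 200 shifted genes: it found 81% of genes shifted by 1 (log2) in the region contrast of each stage, 92% over both stages, 85% and 84% in the stage contrasts of open and closed tissue, and 55% in the interaction. The simulated noise was independent between genes, while in the data the main component held 61.7% of the residual variance. These rates thus do not cover effects that the genes of an array share. Other splits of the arrays were fitted with limma in R. Tallies of these splits, figures and rank tests used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.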

Results

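Expression was measured on 11 arrays of neural tissue from C57BL/6 mouse embryos: open neuroepithelium at E8.5 (n = 3) and E9.5 (n = 3), and closed neural tube at E8.5 (n = 2) and E9.5 (n = 3). Each array came from tissue pooled by litter, and their number limits the precision. Differences are log2, closed minus open or E9.5 minus E8.5, with the standard error (SE) of the model. Where a group mean lay near background, below the filter of 4.3, the size of the difference depends on that background and is not ranked. The closed tissue lay rostral to the open tissue, so closure and axial level differ together in every comparison of the regions. Tissue was taken relative to the junction at each stage, so that axial level can also differ between the stages.

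In a principal component analysis of 13341 genes, component 1 held 44% of the variance and separated open from closed arrays at both stages. Component 2 held 22.7%. RNA quality differed between arrays: the 3-prime signal of the Gapdh and Actb control probe sets exceeded the 5-prime signal by 2.20 and 2.48 (log2) in open E9.5 replicates 1 and 2. In the other 9 arrays it did so by 1.14 to 1.82, with closed E8.5 replicates 1 and 2 at 1.82 and 1.18. Component 2 followed this signal: arrays with scores above 0 had 1.14 to 1.32, and arrays with scores below 0 had 1.44 to 2.48. The main component of the residuals held 61.7% of the residual variance. In closed E8.5 replicate 2, 3 somite genes were higher than in closed E8.5 replicate 1: Meox1 was 8.11 against 6.30, Foxc2 6.50 against 4.08, and Twist1 5.90 against 4.15. The 9 tested genes of the somite list were not tested as a set for this array. These genes were looked at after their values were seen.

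At E8.5 the question was which genes differ between closed neural tube (n = 2) and open neuroepithelium (n = 3). The transcription factor genes Pax6 (log2 difference 3.83, SE 0.18, adjusted p = 2.08e-07), Olig2 (4.08, SE 0.31) and Zic1 (5.29, SE 0.24) were higher in closed tissue, while Sox2 differed by 0.10 (SE 0.10, adjusted p = 0.85). Aldh1a2, which makes retinoic acid, was higher in closed tissue (3.50, SE 0.13), and Cyp26a1, which degrades it, was lower (-4.11, SE 0.27). The growth factor genes Fgf8 (-4.37, SE 0.23) and Fgf17 (-5.28, SE 0.50) were lower in closed tissue. The homeobox genes Evx1 (-4.81, SE 0.24) and Cdx2 (-3.51, SE 0.25) and the Wnt agonist Rspo3 (-4.07, SE 0.21) had the same direction. The nuclear receptor gene Nr2f1 was higher in closed tissue (5.40, SE 0.20). Group means below 4.3 were those of Nr2f1 (3.46), Zic1 (3.26), Olig2 (3.65) and Prdm8 (3.87) in open tissue and of Fgf17 (3.21), Fgf8 (3.84) and Gad1 (3.33) in closed tissue. The gene ccdc198 (5.46, SE 0.34), the secreted hedgehog-release factor Scube2 (4.55, SE 0.24) and Prdm8 (4.15, SE 0.17) were also higher in closed tissue. Gad1, which makes the transmitter GABA, was lower there (-4.60, SE 0.21), as was Tril (-4.11, SE 0.19).

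**Figure D1:**
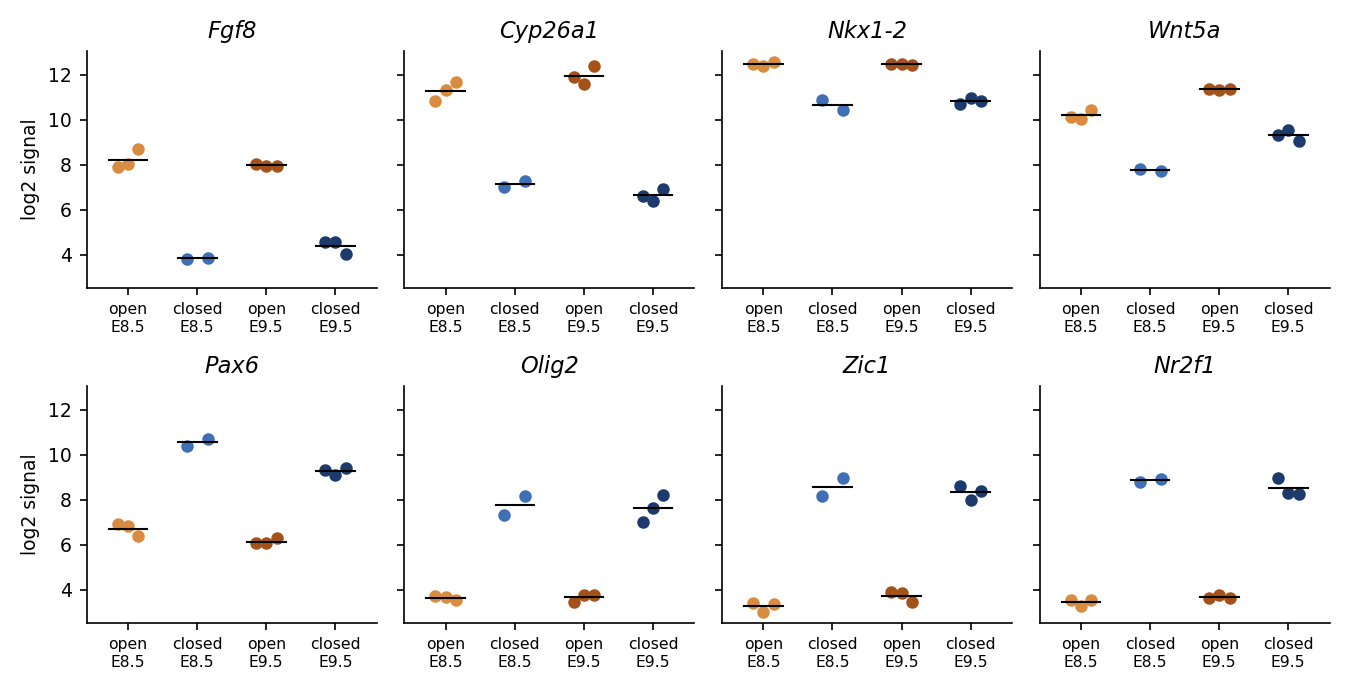
Log2 signal of 8 genes in each array, by tissue and stage, with the group mean as a bar. At E8.5 Fgf8 differed by -4.37 and Pax6 by 3.83 (closed minus open), and at E9.5 by -3.59 and 3.13.

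Of 23 tested caudal progenitor genes at E8.5, 15 were lower in closed tissue, 1 was higher and 7 did not pass (17 lower and 2 higher adjusted over the list alone). Nkx1-2 (-1.83), which marks the preneural epithelium, and Wnt5a (-2.41) were lower, and the activin antagonist Fst (1.27) was the member that moved against the list. The list median was -1.79 (camera adjusted p = 4.64e-23, and 0.00374 with an estimated correlation). Hox genes of paralogue groups 6 to 9 were lower in 8 of 9 (9 adjusted over the list alone), with Hoxa9 at -2.63 and Hoxd8 at -3.11 (median -1.90, adjusted p = 5.08e-17). Of 23 neural progenitor genes, 14 were higher, among them Sox1 (2.97), and Gpm6a (-2.15) was lower (15 higher and 1 lower adjusted over the list alone, median 1.15, adjusted p = 6.11e-16). Of 22 floor plate and hedgehog response genes, 12 were higher, including Nkx6-1 (2.97) and Spon1 (2.78), while the ligand gene Shh itself was lower (-0.89, SE 0.14). For that list 15 were higher and 2 lower adjusted over the list alone (median 0.72, adjusted p = 2.73e-12).

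Among epithelial genes at E8.5, 10 of 23 surface ectoderm and epithelium genes were lower in closed tissue and 1 was higher (12 and 1 adjusted over the list alone), with a median of -0.47 (adjusted p = 1.46e-08). Grhl3, which the mouse needs for closure of the posterior neuropore, differed by -1.97 (SE 0.23), and the protease inhibitor gene Spint2 by -1.58 (SE 0.13). The tight junction gene Cldn9 was lower as well (-2.60, SE 0.21). Cholesterol synthesis genes were higher in closed tissue at E8.5 in 5 of 18 (10 adjusted over the list alone), with Stard4 at 1.20 and Hmgcs1 at 0.52 (median 0.45, adjusted p = 7.15e-08). Of 17 neural crest genes, 8 were higher, with Ednrb at 4.20, and Ngfr (-0.99) was lower (9 higher and 2 lower adjusted over the list alone, median 0.82, adjusted p = 3.3e-05). Of 20 retinoic acid pathway genes, 9 were higher, including Meis1 (3.09), and 3 were lower, including Cyp26a1 and Rxrg (-0.88). The same numbers passed adjusted over the list alone (median 0.43, adjusted p = 0.000454).

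Of 25 FGF and MAPK feedback genes at E8.5, 13 were lower in closed tissue and 6 higher (13 and 7 adjusted over the list alone), with a median of -1.06 (adjusted p = 0.001, and 0.0671 with an estimated correlation). Il17rd (-3.10), an FGF feedback inhibitor, was lower like Fgf8, while Fgf15 (3.12) and Fgfr2 (3.81) were higher. Of 15 presomitic mesoderm genes, 6 were lower, among them the segmentation clock gene Hes7 (-3.87), and Aldh1a2 and Pcdh8 (4.23) were higher (6 and 2 adjusted over the list alone, median -0.23, adjusted p = 0.0026). The death and arrest genes Pmaip1 (-2.31, SE 0.15) and Cdkn1a (-2.17, SE 0.20) were 2 of 4 lower members of 20 apoptosis genes (4 adjusted over the list alone). The apoptosis median was -0.03 and its adjusted p of 0.0308 became 0.0985 with an estimated correlation, 0.051 without open E8.5 replicate 2, 0.0898 without closed E8.5 replicate 1 and 0.0889 with the 3-prime to 5-prime signal in the model.

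Another 4 lists passed at E8.5 with the preset but not with an estimated correlation. With fry the adjusted p was 0.078 for notochord, 0.0119 for early embryonic genes, 7.81e-05 for claudins and 0.00079 for DNA replication. Notochord had a median of -0.41 (6 of 12 lower, 1 higher, and 6 and 2 adjusted over the list alone, adjusted p = 0.0308), 0.463 with an estimated correlation, 0.0642 without open E8.5 replicate 2, 0.473 without closed E8.5 replicate 1 and 0.137 with the 3-prime to 5-prime signal in the model. In it Cav1 (-0.94) was lower and Sox9 (1.24) higher. Early embryonic and let-7 regulated genes had a median of -0.13 (3 of 17 lower, 1 higher, and 4 and 1 adjusted over the list alone, adjusted p = 0.0152), 0.14 with an estimated correlation and 0.0825 without closed E8.5 replicate 2. Claudins had a median of -0.13 (2 of 8 lower, 2 adjusted over the list alone, adjusted p = 0.0425), 0.12 with an estimated correlation, 0.0762 and 0.0568 without open E8.5 replicates 1 and 3, and 0.151 without closed E8.5 replicate 2. DNA replication had a median of 0.10 with 0 of 29 members past the threshold (adjusted p = 0.0476), 0.103 with an estimated correlation. Its adjusted p was 0.0717, 0.0683 and 0.0568 without open E8.5 replicates 1, 2 and 3, and 0.132 and 0.127 without closed E8.5 replicates 1 and 2.

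The E8.5 comparison of regions gave 958 genes past the threshold, 507 higher and 451 lower in closed tissue, of which 484 differed by at least 1. It gave 1520 with the 3-prime to 5-prime signal in the model and 1850 with the main component of the residuals. Groups did not overlap for 27.5% of all genes, against 20% by chance. Of 38 lists, 15 passed, and 9 also passed with an estimated correlation: caudal progenitor, Hox paralogues 6 to 9, neural progenitor, floor plate and hedgehog response, surface ectoderm and epithelium, cholesterol synthesis, neural crest, retinoic acid pathway and presomitic mesoderm. Their camera adjusted p then lay between 0.00374 (caudal progenitor) and 0.0455 (presomitic mesoderm), larger than with the preset correlation. With replicate numbers as blocks Vangl2, a planar cell polarity gene, passed (0.54, adjusted p = 0.0262, against 0.603 without blocks). The 23 lists that did not pass had medians from -0.16 to 0.35, among them planar cell polarity (6 higher and 5 lower of 30, median 0.09, adjusted p = 0.959). Hypoxia response came nearest to passing (median -0.16, adjusted p = 0.0501). It passed with quantile normalization (0.0439) and array weights (0.0295), and had 0.493 with an estimated correlation. Neural tube closure mutants had 5 higher and 5 lower of 65 (median 0.07, adjusted p = 0.444). With 2 closed arrays, a gene that changes in 1 of them cannot be separated from array noise.

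At E9.5 the same question was asked with 3 arrays in each region. Pax6 (3.13, SE 0.16), Olig2 (3.95, SE 0.28), Zic1 (4.58, SE 0.22) and Nr2f1 (4.82, SE 0.18) were again higher in closed tissue. Rfx4 (3.95, SE 0.15) and Pou3f3 (3.90, SE 0.18), transcription factors of neural progenitors, were higher too. The proneural gene Neurog2 differed by 2.78 (SE 0.16, adjusted p = 4.24e-07) and the Notch target Hes5 by 2.29 (SE 0.22). Cyp26a1 (-5.28, SE 0.24) and Fgf17 (-4.64, SE 0.45) were lower in closed tissue. Open tissue was below 4.3 for Nr2f1 (3.68), Zic1 (3.73) and Olig2 (3.66). The limb-level and tail-level Hox genes Hoxd10 (-4.22, SE 0.51) and Hoxa11 (-3.41, SE 0.22) were lower in closed tissue. Fgf8 (-3.59, SE 0.20), Fgf18 (-4.09, SE 0.30) and Lmo2, a transcription cofactor of blood and vessel progenitors (-4.21, SE 0.18), were lower as well. Cdkn1a, which arrests the cell cycle, differed by -3.15 (SE 0.18).

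Of 23 neural progenitor genes at E9.5, 16 were higher in closed tissue and Gpm6a (-1.41) was lower (16 and 3 adjusted over the list alone, median 0.78, camera adjusted p = 4.42e-14). Of 22 floor plate and hedgehog response genes, 13 were higher, with Nkx6-1 at 3.33 and Spon1 at 3.31, and 1 was lower (15 and 1 adjusted over the list alone, median 0.80, adjusted p = 7.23e-14). Of 23 caudal progenitor genes, 14 were lower, including Evx1 (-4.14) and Nkx1-2 (-1.63), while Fst (3.11) was higher (16 and 1 adjusted over the list alone, median -1.50, adjusted p = 1.44e-11). Hox genes of paralogue groups 10 to 13 were lower in 6 of 7 (6 adjusted over the list alone, median -2.09, adjusted p = 1.38e-07, and 0.0612 with an estimated correlation). Of 12 listed members 7 were tested, and a gene low in all groups could fail the filter. Neural crest genes were higher in 8 of 17, with Ednrb at 4.81, and lower in 1 (12 and 3 adjusted over the list alone, median 0.73, adjusted p = 1.52e-07). Of 20 retinoic acid pathway genes, 8 were higher, with Aldh1a2 at 2.87 and Meis1 at 3.10, and 2 were lower (10 and 2 adjusted over the list alone, median 0.36, adjusted p = 2.73e-07).

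Cholesterol synthesis genes were lower in closed tissue at E9.5 in 6 of 18 and higher in 0 (10 lower adjusted over the list alone, median -0.42, adjusted p = 1.77e-06, and 0.0846 with an estimated correlation). Surface ectoderm and epithelium genes were lower in 7 of 23, with Grhl3 at -1.72 and Spint2 at -1.18, while Tfap2c (1.89) was higher (8 and 1 adjusted over the list alone, median -0.26, adjusted p = 0.00597, and 0.0906 with an estimated correlation). The surface ectoderm call also ended with a filter at the 60th percentile (adjusted p = 0.0694). Neurogenesis genes were higher in 7 of 27, with Neurog2, Neurog3 (1.21) and Gadd45g (1.95), and lower in 2, with Mnx1 at -2.25 (9 and 3 adjusted over the list alone). That list had a median of 0.13 and an adjusted p of 0.00597, which became 0.0767 with an estimated correlation, 0.199 with a filter at the 60th percentile and 0.0664 with the mean of all probe sets.

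Another 7 lists passed at E9.5 by smaller margins, and none of them did so with an estimated correlation. Presomitic mesoderm (6 of 15 lower, 2 higher, median -0.52) had an adjusted p of 0.0206, 0.0976 with an estimated correlation and 0.0534 without open E9.5 replicate 3. FGF and MAPK feedback (10 of 25 lower, 4 higher, median -0.44) had 0.0266, 0.176 with an estimated correlation, 0.0729 without open E9.5 replicate 3 and 0.0673 without closed E9.5 replicate 1. Apoptosis (4 of 20 lower, with Pmaip1 at -1.52, median -0.09) had 0.0386, 0.107 with an estimated correlation, 0.129 without open E9.5 replicate 3 and 0.0685 without closed E9.5 replicate 1. Early embryonic and let-7 regulated genes (4 of 17 lower, with Sall4 at -0.72, median -0.28) had 0.0386 and 0.224 with an estimated correlation. Without open E9.5 replicate 1 that value was 0.0533, and without closed E9.5 replicates 1 and 3 it was 0.0958 and 0.0574. With the 3-prime to 5-prime signal in the model it was 0.0805 (median -0.21), and without open E9.5 replicates 1 and 2 together 0.123 (median -0.085). Blood (1 of 7 lower, median -0.52) had 0.0386, 0.284 with an estimated correlation, 0.0533 and 0.0729 without open E9.5 replicates 1 and 3, and 0.198 without closed E9.5 replicate 3. It had 0.0886 with the 3-prime to 5-prime signal and 0.068 without open E9.5 replicates 1 and 2 together (median -0.32). Cell cycle exit (4 of 13 higher, with Gas1 at 1.04, 2 lower, median 0.33) had 0.0472, 0.224 with an estimated correlation and 0.0548 with replicate blocks. Its value was 0.0549 without open E8.5 replicate 3, 0.112 without open E9.5 replicate 3 and 0.103 without closed E9.5 replicate 1. DNA replication (1 of 29 higher, median 0.12) had 0.0472 and 0.107 with an estimated correlation, and up to 0.103 without closed E9.5 replicate 1. It also lost the call without open E8.5 replicates 1, 2 and 3 (0.0515, 0.0502 and 0.0521), open E9.5 replicates 1 and 3 (0.0559 and 0.0698) and closed E9.5 replicate 3 (0.0508), and without open E9.5 replicates 1 and 2 together (median 0.045, 0.122). Lower and higher members adjusted over the list alone were 6 and 3 for presomitic mesoderm, 13 and 4 for FGF and MAPK feedback, 4 and 0 for apoptosis, 7 and 0 for early embryonic genes, 1 and 0 for blood, 3 and 5 for cell cycle exit, and 0 and 1 for DNA replication.

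The E9.5 comparison of regions gave 1139 genes past the threshold, 367 higher and 772 lower in closed tissue, of which 454 differed by at least 1. With replicate numbers as blocks it gave 2222, with array weights 3423, with the 3-prime to 5-prime signal in the model 1765, with the residual component 2864, and without open E9.5 replicates 1 and 2 together 603. The array weights favoured open E9.5 replicate 1 (6.28, against 0.74 and 0.31 for replicates 2 and 3). Groups did not overlap for 22.5% of all genes, against 10% by chance. Of 38 lists, 16 passed, and 5 also passed with an estimated correlation: neural progenitor, floor plate and hedgehog response, caudal progenitor, neural crest and retinoic acid pathway. The camera adjusted p was then 0.0105 for neural progenitor, 0.0112 for caudal progenitor and 0.0243 for neural crest, larger than with the preset correlation. Blocking changed 3 anchor genes: Vangl2 (0.68, adjusted p = 0.00126 against 0.276), Shroom3, which drives apical constriction (-0.56, 0.00431 against 0.0598), and Zic2 (-0.55, 0.0113 against 0.324). It also brought the apical junction and actomyosin list past the threshold (1 higher and 5 lower of 49, median -0.11, adjusted p = 0.0437 against 0.0527). Without blocks, that list had 0.358 with an estimated correlation.

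The 22 lists that did not pass at E9.5 had medians from -0.38 to 0.20. Hox paralogues 6 to 9 were among them (1 higher and 2 lower of 9, median -0.25, adjusted p = 0.206), but passed with the 3-prime to 5-prime signal in the model (median -0.32, adjusted p = 0.0347). So did Hox paralogues 1 to 5 (median -0.11, adjusted p = 0.113), with -0.17 (0.0183). Without open E9.5 replicates 1 and 2 together, which leaves 1 open E9.5 array, the medians of these 2 lists were -0.41 and -0.29. Other lists that did not pass were planar cell polarity (6 higher and 9 lower of 30, median 0.01, adjusted p = 0.945) and Wnt response (5 higher and 5 lower of 23, median -0.01, adjusted p = 0.534). Within planar cell polarity, Wnt5a (-2.04) and Dact1 (-1.19) were lower while Fzd7 (2.51) and Ankrd6 (1.68) were higher. For planar cell polarity the mean was -0.03, below 0 where the median was above it, and for Wnt response the test direction was up while the median and the mean were both below 0. Extracellular matrix and integrins had 5 higher and 8 lower of 38 (median 0.01, mean -0.04, adjusted p = 0.858), with Itga8 at 1.74 and Has2, which makes hyaluronan, at -1.70. Dorsal neural tube and BMP response had 8 higher, with Wnt4 at 2.91, and 4 lower, with Zic5 at -1.05, of 27 (median 0.08, adjusted p = 0.0799). Notch pathway had 3 higher and 3 lower of 28 (median -0.09, adjusted p = 0.73), with Dll3 at -2.28. Somite genes had 1 lower of 9 (median -0.15, adjusted p = 0.233), and lateral and intermediate mesoderm 1 lower of 8 (median 0.02, mean -0.04, adjusted p = 0.858). Endoderm had 2 higher and 1 lower of 11 (median -0.06, mean 0.09, adjusted p = 0.717), and folate and one-carbon 0 of 24 (median 0.01, mean -0.05, adjusted p = 0.858). Mitosis (0 of 28, median 0.02, adjusted p = 0.534), ribosomal protein (0 of 24, median 0.06, adjusted p = 0.122), oxidative phosphorylation (1 lower of 28, median 0.03, adjusted p = 0.509) and endothelium (1 higher and 1 lower of 13, median 0.13, adjusted p = 0.102) did not pass.

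**Figure D2:**
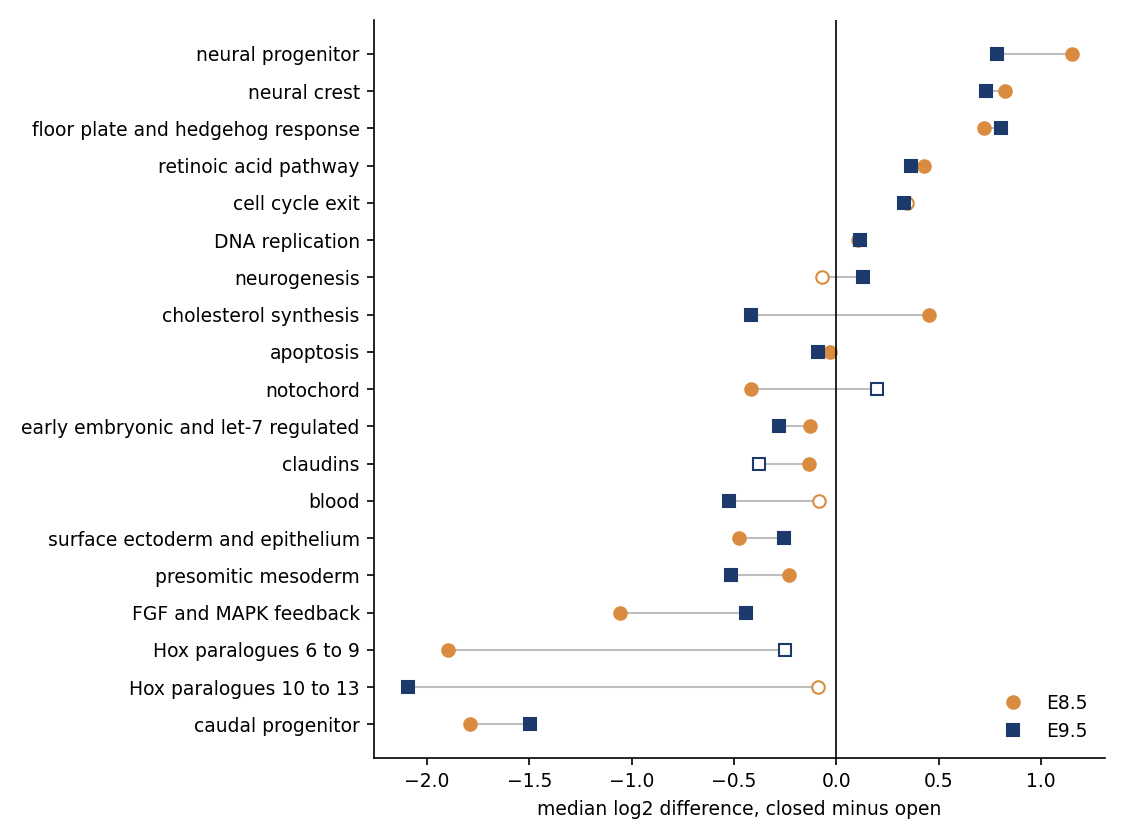
Median log2 difference (closed minus open) of each gene list that passed at E8.5 (circles) or E9.5 (squares), filled where the adjusted p of camera was under 0.05. The caudal progenitor list lay at -1.79 and -1.50, and cholesterol synthesis lay on opposite sides of 0, at 0.45 and -0.42.

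Over both stages together, 1594 genes differed between the regions, 685 higher and 909 lower in closed tissue (2909 with the residual component, and 427 differed by at least 1). The comparisons at E8.5 and E9.5 share no arrays: 244 genes were higher in closed tissue in both, against 13.9 expected for independent calls, 299 were lower in both, against 26.1, and 8 had opposite directions. The expected counts do not allow for the estimate of the spread that both comparisons share. Over the mean of the stages Fgf8 differed by -3.98 (SE 0.15), Cyp26a1 by -4.69 (SE 0.18), Cdx2 by -2.78 (SE 0.17) and Grhl3 by -1.84 (SE 0.15). Aldh1a2 (3.18, SE 0.09), Pax6 (3.48, SE 0.12), Olig2 (4.02, SE 0.21) and Pax3 (1.63, SE 0.12) were higher in closed tissue. Of 38 lists, 13 passed, and 7 also did so with an estimated correlation: caudal progenitor (17 of 23 lower, median -1.59), neural progenitor (16 of 23 higher, median 0.79), floor plate and hedgehog response (14 of 22 higher, median 0.75), Hox paralogues 6 to 9 (7 of 9 lower, median -0.93), surface ectoderm and epithelium (10 of 23 lower, median -0.36), neural crest (9 of 17 higher, median 0.71) and retinoic acid pathway (11 of 20 higher, median 0.48). With replicate blocks Vangl2 (0.61, adjusted p = 0.000385 against 0.146) and Zic2 (-0.51, 0.00356 against 0.213) passed. So did the claudin list (median -0.27, 0.0407 against 0.0647) and Hox paralogues 1 to 5 (median -0.19, 0.0439 against 0.133). Both also passed with the 3-prime to 5-prime signal in the model (medians -0.23 and -0.21, 0.0419 each), and Hox paralogues 1 to 5 without open E9.5 replicates 1 and 2 together (-0.24, 0.0448). Without blocks these lists had 0.145 and 0.421 with an estimated correlation.

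In open neuroepithelium the question was which genes differ between E9.5 and E8.5, with 3 arrays at each stage. Hoxc10 rose by 6.60 (SE 0.37, adjusted p = 4.05e-06), Hoxd10 by 6.03 (SE 0.51), Hoxa10 by 5.18 (SE 0.32) and Hoxa11 by 3.85 (SE 0.22). At E8.5 the means of Hoxd10 (3.22), Hoxa10 (4.30) and Hoxa11 (4.18) in open tissue lay at or below the filter of 4.3. The nuclear receptor gene Nr6a1, a trunk-stage regulator, changed by -3.51 (SE 0.19), and Hoxb9 (-1.31, SE 0.13) and Hoxc8 (-1.38, SE 0.15) were lower too. The embryonic globins Hbb-y (5.18, SE 0.66) and Hba-x (2.35, SE 0.29), which red blood cells make, rose, so that blood in the samples can contribute to these. The lipase gene Lpl (2.87, SE 0.21) and Chst15 (3.50, SE 0.32), a sulfotransferase of chondroitin chains, rose too. Ptprz1 (-2.87, SE 0.20), the receptor gene Ret (-2.34, SE 0.20) and the neurofilament gene Nefl (-1.57, SE 0.16) were lower at E9.5. The hyaluronan synthase gene Has2 (1.78, SE 0.17) and the progenitor gene Sox1 (1.68, SE 0.15) were higher. Wnt8a (-1.47, SE 0.14), expressed at the caudal end, was lower, and Wnt5a (1.16, SE 0.14) higher.

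Among lists in open tissue, Hox paralogues 10 to 13 rose in 6 of 7 (6 adjusted over the list alone, median 3.85, camera adjusted p = 8.81e-13). Of 12 listed members 7 were tested. A member low in all groups could fail the filter, so that 6 of 7 is not a share of the whole list. Cholesterol synthesis rose in 9 of 18, with Hmgcs1 at 0.81 and Sc5d at 0.87 (13 adjusted over the list alone, median 0.56, adjusted p = 9.22e-12). Surface ectoderm and epithelium genes were lower in 3 of 23, with Esrp1 at -1.69 (10 adjusted over the list alone, median -0.31, adjusted p = 7.61e-05), and retinoic acid pathway genes in 3 of 20, with Nr6a1 and Rxrg at -1.47 (6 lower and 2 higher adjusted over the list alone, median -0.21, adjusted p = 0.000885). These 4 lists passed with an estimated correlation as well. Neurogenesis was lower in 5 of 27 (6 adjusted over the list alone, median -0.18, adjusted p = 0.00214, and 0.0705 with an estimated correlation). Blood rose in 4 of 7 (4 adjusted over the list alone, median 1.13, adjusted p = 0.000303, and 0.15 with an estimated correlation).

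Glycolysis (2 of 21 lower, with Pfkp at -1.90, median -0.34) and notochord (3 of 12 lower, with Cav1 at -0.90, median -0.35) passed in open tissue with adjusted p of 0.000303 and 0.00214, and with 0.424 and 0.363 under an estimated correlation. Both calls ended with the 3-prime to 5-prime signal in the model (0.322 and 0.194) and without open E9.5 replicates 1 and 2 together (0.418 and 0.103). Dissociation response genes rose in 4 of 20 (5 adjusted over the list alone, median 0.21, adjusted p = 0.00835, and 0.286 with an estimated correlation), and without the same 2 arrays the adjusted p was 0.07. Hypoxia response was lower in 5 of 18, with Higd1a at -1.01 and Slc2a1 at -0.73 (median -0.17, adjusted p = 0.00982, and 0.424 with an estimated correlation). Its value was 0.0683 without open E8.5 replicate 3 and 0.0615 without open E9.5 replicate 3. Hox paralogues 1 to 5 rose in 4 of 13, with Hoxa5 at 1.01 (median 0.20, adjusted p = 0.00964, 0.271 with an estimated correlation and 0.0935 without open E9.5 replicate 3). Caudal progenitor genes were lower in 3 of 23 and higher in 1 (median -0.23, adjusted p = 0.0303, and 0.363 with an estimated correlation). That value was 0.103 without open E8.5 replicate 3 and 0.144 without open E9.5 replicate 2. Lower and higher members adjusted over the list alone were 2 and 1 for glycolysis, 5 and 0 for notochord, 5 and 0 for hypoxia response, 1 and 5 for Hox paralogues 1 to 5, and 4 and 1 for caudal progenitor. The caudal progenitor call also ended with the 3-prime to 5-prime signal in the model (median -0.10, 0.338) and without open E9.5 replicates 1 and 2 together (-0.12, 0.52).

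The comparison of stages in open tissue gave 670 genes past the threshold, 481 higher and 189 lower at E9.5, of which 219 differed by at least 1. This number depended on single arrays: 367 and 422 without open E8.5 replicates 1 and 3, and 436, 414 and 1262 without open E9.5 replicates 1, 2 and 3. It was 182 without open E9.5 replicates 1 and 2 together, 1006 with the 3-prime to 5-prime signal in the model and 2841 with the residual component. Array weights gave 4296, with 2179 higher and 2117 lower, and lean on open E9.5 replicate 1 (weight 6.28, against 0.74 and 0.31 for replicates 2 and 3). With the signal in the model 529 of the 670 genes passed. Groups did not overlap for 21.8% of all genes, against 10% by chance. The other 26 lists did not pass (medians from -0.13 to 0.12), including mitosis, ribosomal protein and oxidative phosphorylation.

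In closed neural tube the same question was asked with 2 arrays at E8.5 and 3 at E9.5. Hoxc10 rose by 6.23 (SE 0.42, adjusted p = 1.39e-05), Hoxd9 by 4.10 (SE 0.36), Hoxd8 by 3.64 (SE 0.23) and Hoxa9 by 2.14 (SE 0.14), with Hoxc10 near background at E8.5 (mean 3.63). Several genes whose signal was highest in closed tissue at E8.5 were lower at E9.5: the fibrinogen gene Fgb (-2.94, SE 0.15), the chloride transporter gene Slc12a5 (-3.15, SE 0.23), Efemp1 (-3.20, SE 0.24), Ephx2 (-2.96, SE 0.21) and ccdc198 (-3.05, SE 0.34), of which Ephx2 (4.22) and Fgb (4.02) reached background at E9.5. The transcription factor gene Pou3f1 (-2.94, SE 0.14) and the Wnt antagonist gene Sfrp5 (-2.90, SE 0.16) moved with them. Selenop (2.55, SE 0.24), Sparcl1 (2.42, SE 0.17) and the cell cycle inhibitor gene Cdkn1c (1.80, SE 0.23) were higher at E9.5. Shh rose by 0.98 (SE 0.14), Pou3f3 by 1.55 (SE 0.20) and the FGF feedback gene Il17rd by 1.97 (SE 0.12). Pax6 (-1.27, SE 0.18), Aldh1a2 (-1.14, SE 0.13) and Rarb, a target of retinoic acid (-1.80, SE 0.28), were lower at E9.5.

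Among lists in closed tissue, Hox paralogues 6 to 9 rose in 5 of 9 (7 adjusted over the list alone, median 1.16, camera adjusted p = 1.45e-17) and retinoic acid pathway genes were lower in 5 of 20 (7 adjusted over the list alone, median -0.29, adjusted p = 5.24e-05). These 2 lists passed with an estimated correlation as well. Hox paralogues 10 to 13 rose in 2 of 7 (3 adjusted over the list alone, median 0.53, adjusted p = 7.96e-07, and 0.143 with an estimated correlation). Cholesterol synthesis was lower in 1 of 18 (3 adjusted over the list alone, median -0.31, adjusted p = 7.54e-05, and 0.196 with an estimated correlation). FGF and MAPK feedback rose in 5 of 25 and was lower in 1, Fgf15 (median 0.20, adjusted p = 0.00958, 0.196 with an estimated correlation). Caudal progenitor rose in 3 of 23 and was lower in 1 (median 0.13, adjusted p = 0.0125, 0.25 with an estimated correlation). Both became 0.0785 without closed E8.5 replicate 1. Hox paralogues 1 to 5 rose in 2 of 13, with Hoxc5 at 1.28 (median 0.08, adjusted p = 0.0152, 0.25 with an estimated correlation), and 0.433 without closed E8.5 replicate 1. Higher and lower members adjusted over the list alone were 6 and 3 for FGF and MAPK feedback, 4 and 1 for caudal progenitor, and 2 and 0 for Hox paralogues 1 to 5.

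Notch pathway (1 of 28 higher, median 0.07), hypoxia response (0 of 18, median -0.26) and blood (0 of 7, 3 higher adjusted over the list alone, median 0.15) passed in closed tissue with adjusted p of 0.0233, 0.0364 and 0.0364. With an estimated correlation these were 0.166, 0.574 and 0.474. Notch was 0.126 without closed E8.5 replicate 1 and 0.0617 without closed E9.5 replicate 3. Hypoxia was 0.348 without closed E8.5 replicate 2, and 0.0777 and 0.0589 without closed E9.5 replicates 2 and 3. Blood was 0.234 and 0.0577 without closed E8.5 replicates 1 and 2, and 0.101 and 0.126 without closed E9.5 replicates 1 and 2. It was 0.0589 with the 3-prime to 5-prime signal and 0.0546 without open E9.5 replicates 1 and 2 together. Endothelium did not pass in either tissue between stages (medians -0.12 in open and -0.01 in closed tissue). Without open E9.5 replicates 1 and 2, which leaves 1 array in that group, its median in open tissue was -0.24. Sox18, an endothelial factor, was lower in closed tissue at E9.5 (-0.99).

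The comparison of stages in closed tissue gave 323 genes past the threshold, 128 higher and 195 lower at E9.5, of which 161 differed by at least 1. It was 210 without closed E8.5 replicate 2, 174 without closed E9.5 replicate 2, 215 with array weights, 730 with the 3-prime to 5-prime signal in the model, 1005 with the residual component and 150 when only these 5 arrays were fitted. Groups did not overlap for 21.2% of all genes, against 20% by chance. The stage comparisons in open and closed tissue share no arrays: 62 genes rose in both, against 4.6 expected, 50 were lower in both, against 2.8, and 9 had opposite directions. The expected counts hold only for independent comparisons. Open and closed arrays of a stage may share litters or RNA quality, and both comparisons use the same estimate of the spread. The overlap is thus not measured against a true chance level. The other 28 lists did not pass in closed tissue (medians from -0.15 to 0.15).

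**Figure D3:**
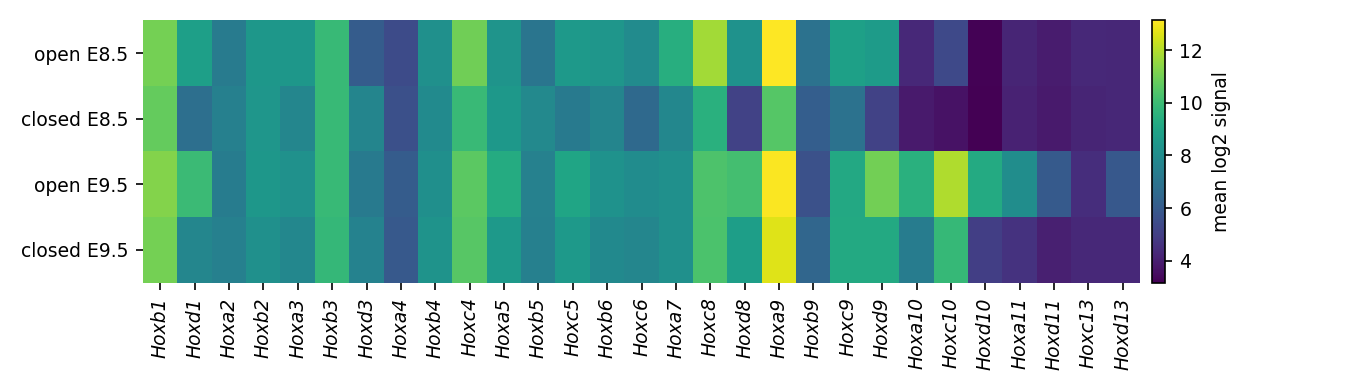
Mean log2 signal of 29 Hox genes in the 4 groups, ordered by paralogue number. From E8.5 to E9.5 Hoxc10 rose by 6.60 in open and 6.23 in closed tissue, and Hoxa9 rose by 2.14 in closed tissue.

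The interaction asked whether the difference between regions itself differs between E9.5 and E8.5, over all 11 arrays. It was positive for Hoxa9 (2.21, SE 0.18, adjusted p = 0.000183), Hoxc8 (2.21, SE 0.23) and Hoxb9 (1.61, SE 0.20), which were lower in closed tissue at E8.5. Shh, the ventral signal of notochord and floor plate, differed by -0.89 at E8.5 and 0.74 at E9.5, an interaction of 1.63 (SE 0.19, adjusted p = 0.00168). The samples held closely attached notochord, so that Shh signal of notochord and of neural tissue cannot be told apart in any of these comparisons. The E9.5 difference of Shh was 0.54 with an adjusted p of 0.135 without open E9.5 replicates 1 and 2 together, which leaves 1 open array. Nr6a1 had an interaction of 2.53 (SE 0.29), with its mean going from 12.25 at E8.5 to 8.74 at E9.5 in open tissue and from 12.03 to 11.06 in closed tissue. Il17rd had one of 1.69 (SE 0.16). Slc12a5 (-3.32, SE 0.31), Scara5 (-2.98, SE 0.25), Fgb (-2.95, SE 0.20), Pth1r (-2.88, SE 0.23), Sfrp5 (-2.68, SE 0.22) and Pou3f1 (-2.16, SE 0.19) had negative interactions. With replicate blocks Cdx2 (1.49, adjusted p = 0.00123 against 0.0712), Cyp26a1 (-1.37, 0.000664 against 0.235) and Pax3 (-1.14, 0.00921 against 0.0531) also passed.

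Hox paralogues 6 to 9 had a positive interaction in 6 of 9 (8 adjusted over the list alone, median 1.71, camera adjusted p = 5.98e-18). Cholesterol synthesis had a negative one in 8 of 18, among them the synthase gene Hmgcs1 and the desaturase gene Sc5d (12 adjusted over the list alone, median -0.91, adjusted p = 1.3e-17). These 2 lists passed with an estimated correlation too (0.00661 and 0.02). Hox paralogues 10 to 13 (2 of 7 lower, median -1.71, adjusted p = 6.36e-06), caudal progenitor (2 of 23 higher, median 0.37, adjusted p = 6.36e-06), notochord (1 of 12 higher, median 0.63, adjusted p = 7.92e-06) and neurogenesis (3 of 27 higher, median 0.31, adjusted p = 0.000397) passed. With an estimated correlation they had 0.119, 0.0685, 0.158 and 0.0613. Adjusted over the list alone, 5 Hox genes of paralogue groups 10 to 13 were lower, and 5 caudal progenitor, 5 notochord and 3 neurogenesis genes were higher with 1 lower in each.

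**Figure D4:**
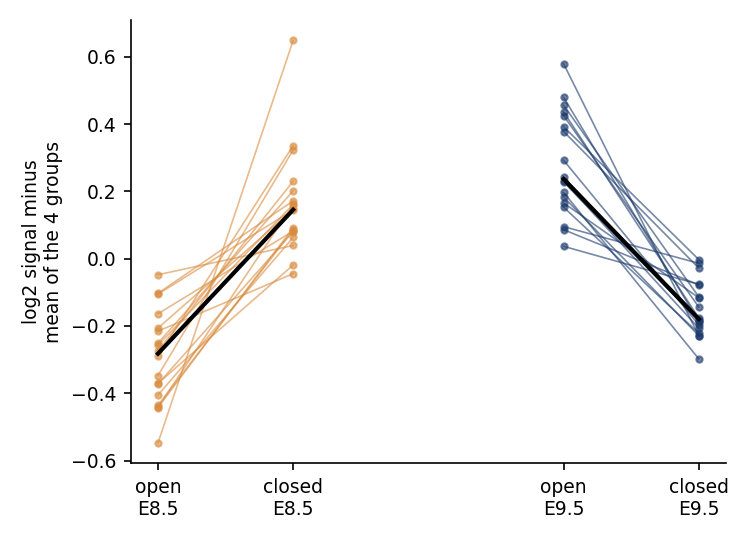
Log2 signal of 18 cholesterol synthesis genes in the 4 groups, each gene less its mean over the groups, with the median in black. The median difference closed minus open was 0.45 at E8.5 and -0.42 at E9.5.

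The interaction gave 167 genes past the threshold, 40 positive and 127 negative. It was 94, 106 and 84 without open E8.5 replicates 1, 2 and 3, 102 without closed E8.5 replicate 2, 100 and 97 without open E9.5 replicates 1 and 2, and 105 and 94 without closed E9.5 replicates 2 and 3. It was 452 with replicate blocks, 297 with the 3-prime to 5-prime signal in the model, 862 with the residual component and 72 without open E9.5 replicates 1 and 2 together. In simulated changes, with noise independent between genes, the test found 55% of genes shifted by 1 and 88% of genes shifted by 2. Smaller interactions would thus often be missed.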

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

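The tests of RNA quality, both tests of the cholesterol synthesis genes and the splits that part all pairs were chosen after the results were seen, while the tests of presomitic mesoderm, protease, blood and the other splits of arrays were planned.

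The results given here were picked because the difference between regions differed between the stages by the interaction test. In all, 167 genes did so. Negative interactions were found for Slc12a5 (-3.32), Scara5 (-2.98), Fgb (-2.95), Pth1r (-2.88), Sfrp5 (-2.68), Pou3f1 (-2.16) and Folr1 (-1.36). Positive ones were found for Nr6a1 (2.53), Hoxc8 (2.21), Hoxa9 (2.21), Il17rd (1.69), Shh (1.63), Hoxb9 (1.61) and Neurog2 (1.10). The calls of Folr1 and Neurog2 were the fragile ones of these 14. Leaving out open E8.5 replicate 1, 2 or 3 gave adjusted p of 0.0648, 0.0953 and 0.102 for Folr1 and 0.138, 0.125 and 0.0567 for Neurog2. Without closed E8.5 replicate 2 they were 0.14 and 0.208. Without open E9.5 replicates 1 and 2 they were 0.0844 and 0.0882 for Folr1, and 0.122 and 0.0771 for Neurog2. Without closed E9.5 replicates 1 and 3 they were 0.0652 and 0.0693 for Folr1, and 0.103 and 0.056 for Neurog2. Neurog2 also had 0.0557 without open E9.5 replicate 3 and 0.109 without closed E9.5 replicate 2.

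Lists with an interaction were Hox paralogues 6 to 9 (median 1.71), cholesterol synthesis (-0.91), Hox paralogues 10 to 13 (-1.71), caudal progenitor (0.37), notochord (0.63), neurogenesis (0.31), glycolysis (0.21), surface ectoderm and epithelium (0.16), FGF and MAPK feedback (0.20), blood (-1.08) and somite (-0.41). With an estimated correlation only Hox paralogues 6 to 9 and cholesterol synthesis of these 11 kept the call. Glycolysis had an adjusted p of 0.00396, 0.706 without closed E8.5 replicate 1, 0.0554 without open E9.5 replicate 2, 0.808 with the 3-prime to 5-prime signal in the model and 0.696 without open E9.5 replicates 1 and 2 together. With these 2 alternatives FGF and MAPK feedback had 0.174 and 0.115, somite 0.174 and 0.35, and blood 0.19 and 0.115, against 0.00696, 0.0497 and 0.0497. Surface ectoderm and epithelium had 0.00474, and 0.109 without closed E8.5 replicate 2. For somite and blood 8 and 6 single arrays ended the calls, with the highest values 0.46 without closed E8.5 replicate 2 for somite and 0.245 without closed E9.5 replicate 3 for blood.

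Caudal progenitor genes were lower in closed tissue at both stages (medians -1.79 and -1.50), and cells of the primitive streak, tail bud or presomitic mesoderm in the open samples are one candidate explanation. The presomitic mesoderm list had medians of -0.23 at E8.5 and -0.52 at E9.5, with an interquartile range over the root of its size of 0.67 and 0.57. Hes7, Dll3 and Rspo3 were higher in open tissue, Aldh1a2 and Pcdh8 were higher in closed tissue, and Msgn1 stayed between 4.35 and 4.86 in all 11 arrays. The members go both ways and the list is small, so that such cells and caudal neural progenitors cannot be told apart. By the dissection the regions also differ in axial level, whose part in this pattern cannot be told apart from that of closure and was not tested.

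Genes differed between E8.5 and E9.5 in both regions, and 3 technical explanations were weighed. The axial level of the tissue can also differ between the stages, which was not tested and cannot be told apart from development. The dissociation response list had a median of 0.21 in open and -0.02 in closed tissue, the blood list 1.13 and 0.15, and the endothelium list -0.12 and -0.01. The longer protease incubation cannot be told apart from development for the dissociation genes, since the design gives each stage its own incubation. For blood, Hbb-y was 5.008 to 8.202 at E8.5 and 11.765 to 12.336 at E9.5 in open tissue. In closed tissue it was 8.43 to 8.88 and 10.609 to 12.13. Red blood cells make such globins, so their rise is not read as a change in neural tissue. The blood list is small, and how far blood adds to other differences was not tested. For RNA quality, the 1262 genes past the threshold without open E9.5 replicate 3 were examined in that array, whose 3-prime to 5-prime signal (1.14) was like that of the open E8.5 arrays (1.26). Of these, 88.1% had the same direction there, with a median ratio of 0.504 to the difference in replicates 1 and 2. The choice of these genes lowers the ratio and the shared E8.5 arrays raise it, so that RNA quality and development cannot be told apart as causes of a part of the difference. With the 3-prime to 5-prime signal in the model, 529 of the 670 genes (79.0%) still passed in open tissue. This argues against that signal as the whole cause. The genes were chosen on the same arrays. The signal comes from the Gapdh and Actb control probe sets, so that other effects of RNA quality are not covered. Without open E9.5 replicates 1 and 2, which leaves 1 array in that group, 171 of the 670 passed.

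Cholesterol synthesis genes were higher in closed than open tissue at E8.5 (median 0.45) and lower at E9.5 (-0.42). The values argue against the 3-prime to 5-prime signal as the whole cause: with this signal of each array in the model, the median interaction was -1.03 and stayed past the threshold. They also argue against an effect of the longer protease incubation shared by both regions, since the list changed by 0.56 in open tissue and by -0.31 in closed tissue (interquartile range over the root of its size 0.09 and 0.06). With an estimated correlation the difference between regions at E9.5 had an adjusted p of 0.0846, and the fall in closed tissue 0.196. The biological differences that the design names, region and stage, remain open and were not tested further.

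Other splits of the arrays were fitted for 3 counts. For the regions at E9.5, the 10 possible splits are too few for a share under 0.05 (1139 genes in the real split, at most 0 in the others, so that 1 split was as large). The same holds for the stages in open tissue (670 genes, at most 0 in the others, 1 split as large). For the regions over both stages, 1 of 100 splits, the real one, gave as many as 1594 genes, and chance is excluded at that share. The highest other split gave 1071 genes, and it followed the 3-prime to 5-prime signal of the arrays and parted 1 pair of replicate numbers. With equal numbers taken as pairs, which the labels do not state, all 32 splits that part all 5 pairs, as the real one does, were also fitted: 1 of them, the real one, gave as many genes (share 0.0312). The highest other of these gave 330 genes, with all 5 pairs swapped, which is close to a mirror of the real split.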

How the results depend on the processing

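The alternatives with the 3-prime to 5-prime signal, with the residual component and without open E9.5 replicates 1 and 2 together were chosen after the data were seen. Counts are given in the order regions at E8.5, at E9.5 and over both stages, stages in open and in closed tissue, and interaction, with main counts of 958, 1139, 1594, 670, 323 and 167. With the 3-prime to 5-prime signal in the model they became 1520, 1765, 2355, 1006, 730 and 297, within 1.5 times only for both stages together. With the residual component they became 1850, 2864, 2909, 2841, 1005 and 862, a rise that follows from taking the largest residual pattern out of the error. With a limit of 1 on the absolute difference, which can only remove genes, they became 484, 454, 427, 219, 161 and 134, the last within 1.5 times. Without open E9.5 replicates 1 and 2 together, which leaves fewer arrays, 603 genes passed at E9.5, 182 in open tissue and 72 in the interaction. With array weights 3423 passed at E9.5, 4296 in open (2179 higher and 2117 lower, against 481 and 189) and 215 in closed tissue. The weight of open E9.5 replicate 1 was 6.28, against 0.74 and 0.31 for replicates 2 and 3. The weighted counts at E9.5 and in open tissue thus lean on that array. With replicate blocks 2222 passed at E9.5, 310 in open tissue, where the numbers do not pair arrays between stages, and 452 in the interaction, and with only the groups compared 150 in closed tissue, where fewer arrays estimate the spread. Leaving out 1 array gave 367 to 1262 in open tissue, 174 to 375 in closed tissue and 84 to 239 in the interaction, and the region counts stayed within 1.5 times (654 to 1098, 789 to 1531 and 1278 to 1773). Quantile normalization, centring, the filters, the mean of probe sets, single probe sets and both eBayes settings kept every count within 1.5 times. With quantile normalization 393 genes were higher and 248 lower in open tissue at E9.5. For the oxidative phosphorylation list in open tissue the direction turned with the 3-prime to 5-prime signal in the model (median 0.14, adjusted p = 0.0328, against -0.06 and 0.806), and the cause was not tested. Of 352 calls of named genes, 279 held with each array left out and 256 under every other alternative, and of 77 calls of lists 51 and 29 did. No named gene reversed. With fry 13 calls of lists ended, such as the interactions of glycolysis (adjusted p = 0.571) and notochord (0.0931). Fry also gained 18 calls, such as claudins (5.39e-05) and Notch pathway (0.00889) between regions at E9.5. Blocks by replicate number ended the interaction of the somite list (median -0.41, adjusted p = 0.0592) and, apart from the values given with the regions and the interaction, changed no other call there. Pseudocounts of 1 and 64 were not run, since the table was on a log2 scale already. Signal near background limits genes such as Hoxc10 at E8.5, whose values of 3.25 to 5.39 lie near the filter.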

Other observations

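The tests given in this part, of litters and of Hox paralogue number, were chosen after the values were seen.

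Some lists that did not pass at E8.5 had members that differed in opposite directions between the regions, among them Wnt response (5 higher and 6 lower of 23), planar cell polarity (6 and 5 of 30) and extracellular matrix and integrins (4 and 5 of 38). Among Wnt response genes, the cyclin gene Ccnd2 (1.01, SE 0.09) was higher in closed tissue, while the feedback inhibitor genes Notum (-2.70, SE 0.36) and Nkd1 (-1.28, SE 0.22) were lower. Among planar cell polarity genes, the receptor genes Fzd7 (2.09, SE 0.25) and Fzd3 (0.83, SE 0.14) were higher, and Dact1 (-1.01, SE 0.13) and Ptk7 (-1.47, SE 0.20) were lower. Among matrix and integrin genes, Fbn2 (1.77, SE 0.20) and Col18a1 (0.88, SE 0.09) were higher and Itgb5 (-1.56, SE 0.15) was lower. Hoxd3 (1.63, SE 0.22) was higher in closed tissue at E8.5, and Hoxc4 (-1.04, SE 0.14) and Hoxc5 (-1.28, SE 0.12) were lower. Ccn2, a gene activated by cell tension that is also a dissociation response gene, was higher in closed tissue (2.44, SE 0.26).

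The collagen genes Col4a1 (-0.89, SE 0.12) and Col18a1 (-0.72, SE 0.09) were lower at E9.5 in closed tissue, while the integrin gene Itga8 was higher (1.33, SE 0.21). In open tissue Fat4, a large cadherin, was higher at E9.5 (1.18, SE 0.16), and Prtg (-1.56, SE 0.12) and Rfx4 (-1.81, SE 0.15) were lower. The glucose transporter gene Slc2a1 was lower at E9.5 in open tissue (-0.73, SE 0.08).

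Sex-linked genes (4 tested, too few for the list test) varied between arrays of a group. Xist was 5.23 in open E9.5 replicate 1 and 6.09 in closed E9.5 replicate 1, against 9.40 to 9.80 in the other E9.5 arrays, and the mean of Eif2s3y, Kdm5d and Uty was 7.69 and 7.60 in these 2 arrays. The hypothesis that arrays of the same number within a stage come from the same litters was tested with the differences in this signal between same-number arrays. Their sum was 4.05, against a median of 12.69 over all 36 arrangements, and 8 of these gave a sum as small (exact permutation p = 0.222). The smallest p possible was 0.0278, and the test leaves the hypothesis open.

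Hox genes of higher paralogue number may change more between the stages, as the values of Hoxc10 and Hoxd10 prompted. Across 29 tested Hox genes, which are not independent replicates, the rank correlation of paralogue number with the E9.5 minus E8.5 difference was 0.377 in open and 0.418 in closed tissue. The permutation p were 0.0443 and 0.0244, and 0.0591 each after adjustment over 4 comparisons, so that neither passed. Hox genes low in all groups could fail the filter and so be missing from this test, which limits it. The exceptions included Hoxb9 (-1.31) and Hoxc8 (-1.38), which were lower in open tissue at E9.5.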
